A study of Homo sapiens with 6 samples.

How the data were processed

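The series holds 6 human transcriptome arrays, 1 for each of 6 xenograft tumours grown from PC9 cells in nude mice. The labels place 3 tumours in a group that carries a short hairpin RNA (shRNA) against KDM1A and 3 in a group with a control shRNA, and describe the tumours of a group as independent. Total RNA (6 µg) was turned into biotinylated cRNA by the standard Affymetrix procedure, per the labels' protocols. Affymetrix Expression Console and Transcriptome Analysis Console are the tools named in the submitters' processing notes. Their versions, the background correction, the normalization between arrays and the summarization of probes are not given in the sources used here.

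The deposited table holds 1 summarized log2 signal for each of 67528 transcript clusters on each array, with values from 1.30 to 13.1. The base of the logarithm is not given in the sources used here. It was taken as 2, the base that Expression Console writes, so every fold value rests on that reading. Array medians lay between 3.31 and 3.41. No further normalization was applied in the fit that is reported first. An array gives no read depth, so the number of arrays limits the precision.

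Gene symbols came from the platform annotation that goes with the table. It listed 25324 transcript clusters, of which 23781 had 1 symbol and 1543 had several. The other 42204 clusters are unnamed here and entered only a test of all clusters. A cluster with several symbols named no gene. Symbols were checked against a table of RefSeq genes (GRCh38.p14), and 0 needed an update. No coordinates are given, because the genome build behind the array's clusters is not given in the sources used here. Where several clusters carried the same symbol (479 genes), the one with the highest mean over the 6 arrays stood for the gene. This left 22465 genes. The table held 0 control probe sets.

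Differences are the mean of the tumours labelled shKDM1A minus the mean of the tumours labelled shControl, on the log2 scale. They were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Standard errors (SE) are the moderated ones of that fit and the SD is the spread of the 3 tumours of a group. For single values a 2-sided exact permutation test is also given; with 3 tumours against 3 its smallest possible p is 0.10. The tumours are independent per the labels, so the p-values for single genes are set against the spread between tumours of a group. Each group came from cells with its own shRNA. Other differences between those cells therefore cannot be told apart from the knockdown.

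The samples, the test, the rule for named genes, the 29 gene lists and most other settings were fixed before the data were examined. The lists came from textbook knowledge, and 647 of their 728 members were tested. A further 42 lay only on clusters with several symbols, such as TIMP2 and RPL3, and 39 were not analysed here. Lists were tested with camera, which asks whether a list's genes rank higher or lower than the other genes, with a preset inter-gene correlation of 0.01 and adjustment over the 29 lists. At the preset correlation its p-value rests mainly on the spread between genes and not on that between tumours. The same test with a correlation estimated from the data was run beside it, as was fry, which asks whether a list's genes move one way on balance. The median of each list was also ranked among 1000 random lists of the same size matched on mean signal.

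KDM1A and TIMP3 are always named. Genes past the adjusted threshold with separated groups were to be named next, up to 10 in each direction by size. Where fewer than 5 passed in a direction, the 5 with the smallest unadjusted p are given as values. From each list described, up to 4 members with the smallest p are named. Genes named outside that rule were chosen after their values were seen, which is stated where they appear.

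The other settings fixed in advance were quantile normalization, centring on array medians, leaving out genes below the median signal of 4.72, the mean of all clusters of a gene, the replicate number as a block, array weights, eBayes with trend and robust estimation, leaving out each tumour, all clusters, an unmoderated F-test, treat against a 1.5-fold change, a rule of unadjusted p with a 2-fold change, an estimated correlation and fry. Cyclic loess normalization and leaving out both tumours numbered 1 were added after the data had been seen, as was the estimated correlation within the other settings. So were 3 lists of genes of other tissues: 25 acinar enzymes of the pancreas, 6 islet genes and 12 secreted proteins of the liver. The acinar list was drawn up after the levels of most of its members had been seen; the islet and liver lists were drawn up before.

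The fit was tested on simulated data in which 50 genes each were shifted by a known fold among the 22465 genes. It recovered 12% of genes shifted 1.2-fold, 88% of those shifted 1.5-fold, 98% of those shifted 2-fold and 100% of those shifted 3-fold, with 4 false calls. Genes were simulated as independent, and the shifted genes of all folds stood in the same set. The adjustment is easier to pass where many genes are shifted. These shares may therefore overstate what the fit recovers where few genes differ or genes are correlated. Camera was tested on 200 simulated lists of 40 genes. With independent genes it called 4.5% of unshifted lists and 100% of lists shifted by -0.2. With genes correlated at 0.552, the value estimated for the cell cycle list, it called 60.5% of unshifted lists at the preset correlation and 3% with an estimated one. No shifted list was simulated for the estimated correlation, so its power was not measured. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.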

Results

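Gene expression was measured in 6 subcutaneous xenograft tumours of PC9 cells, a human lung adenocarcinoma line with an activating EGFR mutation. The cells stably expressed either an shRNA against KDM1A, which encodes the histone demethylase LSD1, or a control shRNA. For each tumour, cells in 100 µL of buffer were placed under the skin of the right axilla of a 5-week-old nude mouse, and the tumour was taken 5 weeks later. Each group held 3 independent tumours. The arrays carry human probes, and mouse RNA from the host tissue can bind some of them. The comparison asks which transcripts differ between tumours of the knockdown cells and control tumours. All 6 arrays were close to one another, with Pearson's r across transcript clusters between 0.994 and 0.997 for every pair; clusters are not independent replicates. The mean root-mean-square log2 difference was 0.15 for the 6 pairs within a group and 0.15 for the 9 pairs between groups.

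KDM1A itself (transcript cluster TC01000292.hg.1) had log2 signals of 7.65, 7.43 and 7.52 in the tumours labelled shKDM1A 1, 2 and 3. The tumours labelled shControl 1, 2 and 3 had 7.49, 8.07 and 7.85. The group means were 7.53 ± 0.11 (SD, n = 3) and 7.80 ± 0.29 (SD, n = 3). The difference of -0.27 (SE 0.13), a level of 0.830 of the control, was within the spread between tumours (limma adjusted p = 0.835; exact permutation p = 0.30). The tumour labelled shControl 1 lay inside the range of the tumours labelled shKDM1A and so went against its label for the targeted gene. All directions given here follow the labels as deposited and carry that reservation. Without the tumour labelled shControl 1 the KDM1A difference was -0.43 (limma adjusted p = 0.121), and without the tumour labelled shControl 2 it was -0.14.

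TIMP3, an inhibitor of matrix metalloproteinases (TC22000248.hg.1), had a log2 signal of 6.56 ± 0.01 (SD, n = 3) in the tumours labelled shKDM1A and 6.43 ± 0.05 (SD, n = 3) in the tumours labelled shControl. Every tumour of the first group lay above every tumour of the second. The difference of 0.13 (SE 0.05), 1.09-fold, did not pass the test (limma adjusted p = 0.835; exact permutation p = 0.10, the smallest that 3 against 3 tumours can give).

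**Figure D1:**
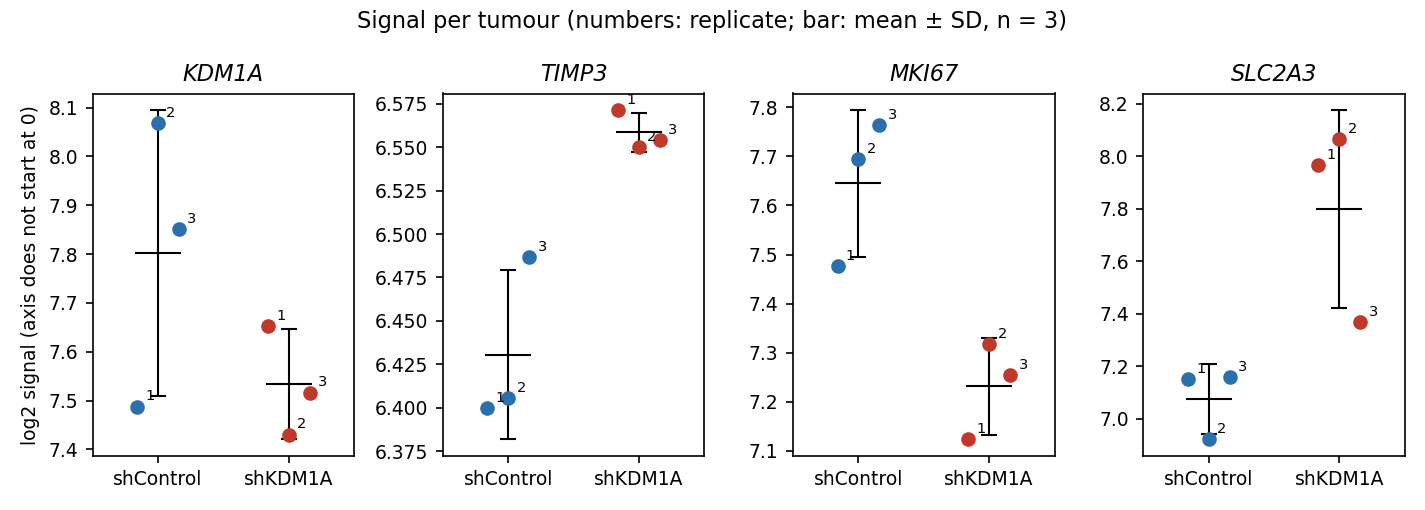
Log2 signal of KDM1A, TIMP3, MKI67 and SLC2A3 in each tumour, by labelled group, with the mean and SD of the 3 tumours as bars. The tumour labelled shControl 1 lies at 7.49 for KDM1A, inside the range of the tumours labelled shKDM1A, and the groups are separated for the other 3 genes; none of the 4 passed the adjusted threshold.

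No single gene passed the adjusted threshold. Of 22465 genes, limma placed 0 higher and 0 lower in the tumours labelled shKDM1A, and the smallest adjusted p was 0.835. An unadjusted p under 0.05 was reached by 1301 genes, where chance alone gives 1123; 597 of them were higher and 704 lower. Centring each array on its median moved the share of higher genes among them from 45.9% to 35.7%. The unmoderated F-test also gave 0 genes after adjustment, with 1050 at an unadjusted p under 0.05. The groups were fully separated for 2189 genes, or 9.74%, where chance gives 10%. A test of all 67528 clusters gave a smallest adjusted p of 0.336. The count at an unadjusted p under 0.05 depended on single tumours: it was 3870 without shControl 1, 752 without shKDM1A 1, 782 without shControl 2 and 695 without shControl 3.

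The 5 genes with the smallest p among those with higher values, none of which passed, were CYRIA, a regulator of Rac1 signalling (log2 difference 0.64, SE 0.11), IGFL3 (0.46), CLTRN (0.47), GPRIN2 (0.29) and the pseudogene P2RX6P (0.31). Among those with lower values, where none passed either, they were the small nuclear RNA pseudogene RNU4-9P (-0.31, SE 0.05), the kinase NUAK2 (-0.39), the microRNA-processing enzyme DICER1 (-0.29), the protocadherin PCDHGA10 (-0.33) and ERVV-2 (-0.28). Unadjusted p-values ran from 0.000270 for CYRIA to 0.000554 for P2RX6P and from 0.000172 for RNU4-9P to 0.000742 for ERVV-2. CYRIA, CLTRN, P2RX6P, RNU4-9P, PCDHGA10 and ERVV-2 were dim, below the median signal of 4.72. Group means of RNU4-9P, PCDHGA10 and ERVV-2 lay between 2.49 and 2.93, near the lower quartiles of the arrays (2.35 to 2.41). A difference of at least 2-fold was seen for 3 genes, chosen after their values were seen. The collagenase MMP13 differed by 1.26 (SE 0.56), the interferon-induced IFI6 by 1.22 (SE 0.55) and the microRNA gene MIR4521 by 1.12 (SE 0.35). Each had overlapping groups and a limma adjusted p of 0.835. MIR4521 was dim as well, with means of 3.99 in the tumours labelled shKDM1A and 2.87 in those labelled shControl.

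**Figure D2:**
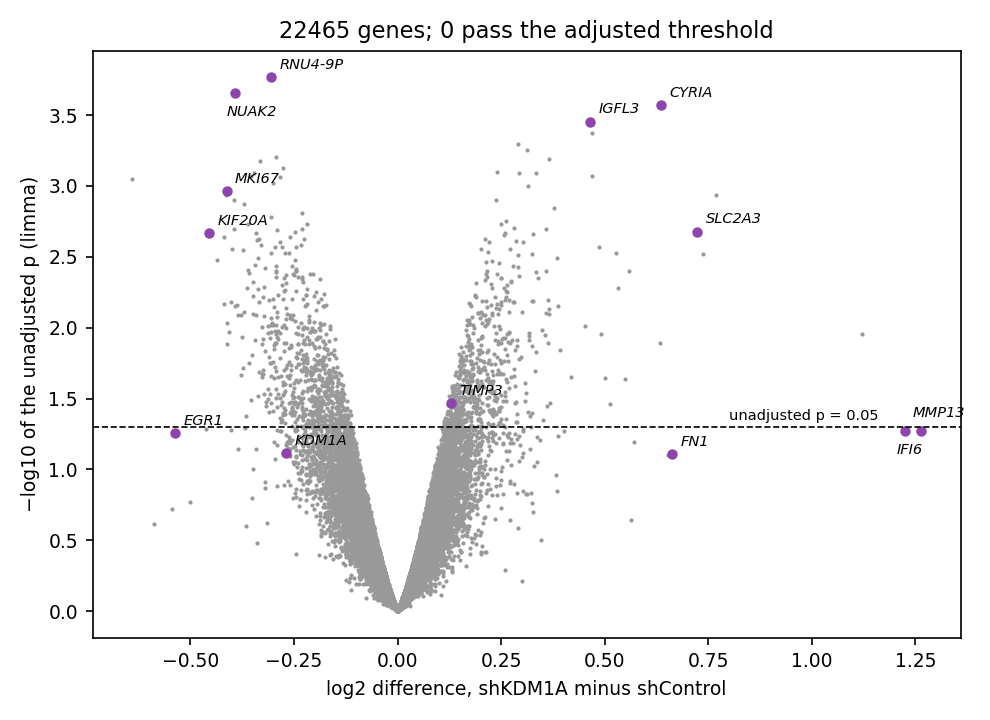
Log2 difference between the tumours labelled shKDM1A and those labelled shControl (horizontal axis) against −log10 of the unadjusted p from limma (vertical axis) for 22465 genes, with selected genes of the report marked in purple and a dashed line at an unadjusted p of 0.05. MMP13 (1.26) and IFI6 (1.22) lie farthest to the right, just below the line (unadjusted p = 0.0538 and 0.0535), and 0 genes pass after adjustment.

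Gene lists were called where no single gene passed, but every list call rested on the preset correlation. In the simulation that setting also called 60.5% of unshifted lists whose genes were correlated at 0.552. The calls therefore do not show a difference beyond the spread between tumours. Camera called 10 of the 29 lists, 3 higher and 7 lower in the tumours labelled shKDM1A. With a correlation estimated from the data it called 0, with a smallest adjusted p of 0.578, and fry also called 0. Among the 10 lists, the unadjusted camera p with an estimated correlation ran from 0.0507 for cell cycle to 0.404 for epithelial genes. Adjustment gave several lists the same value, so equal adjusted values do not mean equal evidence. The power of that version was not measured, so the lost calls do not show that the lists are unchanged.

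The cell cycle and proliferation list stood furthest from the other genes. All 40 of its tested members had lower means in the tumours labelled shKDM1A, with a median log2 difference of -0.22, or 0.859-fold (camera adjusted p = 3.59e-27; adjusted p = 0.578 with an estimated correlation). MKI67, the proliferation marker, differed by -0.41 (SE 0.09), the mitotic kinesin KIF20A by -0.45 (SE 0.10), the chromosomal passenger CDCA8 by -0.26 (SE 0.06) and cyclin B2 (CCNB2) by -0.34 (SE 0.08). Adjusted over the list alone, 20 members passed; adjusted over all genes, 0 did. The mean deviation of the list was -0.20, -0.08 and -0.05 in the tumours labelled shKDM1A 1, 2 and 3, against 0.00, 0.21 and 0.13 in those labelled shControl (exact permutation p = 0.10, the smallest possible). The list median lay below all 1000 matched random lists, which were not matched on the correlation of 0.552 estimated within this list. Among the other called lists, TGF-beta targets ranked at percentile 35.1 and epithelial genes at 16.9, inside the random lists. The rest ranked at 2.1 or below, or at 99.7 or above. The 20 cell cycle members that passed became 0 without shKDM1A 1, shControl 2 or shControl 3, 7 without shKDM1A 2 and 26 without shControl 1, while camera called the cell cycle list in each of these fits at the preset correlation. With an estimated correlation it called the list in none of the 6 fits without 1 tumour, with adjusted p-values from 0.348 to 0.902. Beside this list, housekeeping genes were lower for 12 of 13 members, epithelial genes lower for 17 of 24 and macrophage and leukocyte genes higher for 19 of 22.

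Replication-dependent histone genes, whose transcripts accumulate in S phase, were lower for 13 of 14 members, with a median of -0.14 (camera adjusted p = 3.00e-05; adjusted p = 0.578 with an estimated correlation). H2BC17 differed by -0.19, H2AC13 by -0.22, the linker histone H1-4 by -0.37 and H2BC14 by -0.17, and 0 members passed over the list alone. The tumour labelled shKDM1A 3 stood with the control tumours for this list, with a mean deviation of 0.08. Without it the median was -0.22 and 3 members passed over the list alone; without shKDM1A 2 the median was -0.09 and 0 passed.

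Interferon-stimulated genes were higher for 35 of 40 members, with a median of 0.08 (camera adjusted p = 3.00e-05; adjusted p = 0.578 with an estimated correlation), and 0 passed over the list alone, against 5 without shKDM1A 3. The median was 0.05 after quantile and 0.06 after cyclic loess normalization, and 0.13 without dim genes, which left 14 members, 13 of them higher. The antiviral membrane proteins IFITM2 (0.24) and IFITM3 (0.32), the virus-tethering protein BST2 (0.24) and IFI6 (1.22) had the smallest p-values. IFI6 varied widely inside the groups, at 7.36, 8.21 and 6.04 in the tumours labelled shKDM1A and 5.76, 5.29 and 6.88 in those labelled shControl. Hypoxia response genes were higher for 28 of 33 members, with a median of 0.06 (camera adjusted p = 0.000286; adjusted p = 0.578 with an estimated correlation). The glucose transporter SLC2A3 differed by 0.72 (SE 0.17) with separated groups, the stress-induced NDRG1 by 0.36, the neuronal enolase ENO2 by 0.23 and FAM162A by 0.11; 0 members passed over the list alone. That count was 7 without shControl 1 and 1 without shKDM1A 3, with medians of 0.10 in both fits, and the hypoxia call was lost without shKDM1A 2 (camera adjusted p = 0.110). Macrophage and leukocyte genes, a list meant for host cells, had higher group means for 19 of 22 members, with a median of 0.07 (camera adjusted p = 0.0277; adjusted p = 0.623 with an estimated correlation), but their tumours overlapped (exact permutation p = 0.40 for the list mean) and 0 passed over the list alone. LAPTM5 differed by 0.18, NCR1 by 0.15, GZMB by 0.13 and C1QC by 0.16. The tumour labelled shControl 1 had the highest mean of that list (0.07), and the call was lost without shKDM1A 1 (0.110), shControl 2 (0.310) or shControl 3 (0.0618) and after quantile (0.0607) or cyclic loess (0.0655) normalization. Without shControl 2 the median was 0.03, with 15 of 22 members higher.

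Cholesterol synthesis genes were lower for 16 of 19 members, with a median of -0.11 (camera adjusted p = 0.000291; adjusted p = 0.623 with an estimated correlation). HSD17B7 differed by -0.25, NSDHL by -0.19, HMGCS1, an early enzyme of the pathway, by -0.39 and IDI1 by -0.21. The difference rested on the tumour labelled shControl 2, whose list mean was 0.27 against 0.02 in shControl 3 and -0.10 in shControl 1; without it the camera adjusted p was 0.364 and the median -0.04. Over the list alone 0 members passed, against 7 without shControl 1, where the median was -0.19. Output genes of EGFR and ERK signalling were lower for 20 of 27 members, with a median of -0.07 (camera adjusted p = 0.00660; adjusted p = 0.578 with an estimated correlation). The ERK phosphatases DUSP4 and DUSP6 differed by -0.26 and -0.18, the transcription factor EGR1 by -0.54 (SE 0.24) and PHLDA1 by -0.18. That call was lost without shKDM1A 1 (0.230), where 14 members were higher and 13 lower, or shControl 2 (0.0767), without both tumours numbered 1 (0.241), and after quantile (0.0607) or cyclic loess (0.0655) normalization.

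Epithelial genes were lower for 17 of 24 members, with a median of -0.07 (camera adjusted p = 0.0277; adjusted p = 0.688 with an estimated correlation). E-cadherin (CDH1) differed by -0.27 and keratin 18 (KRT18) by -0.15, whereas TJP3 (0.12) and OVOL1 (0.12) were higher in every tumour labelled shKDM1A. After cyclic loess normalization 12 members were higher and 12 lower (adjusted p = 0.807), and the call was also lost without shKDM1A 1 (0.534), shControl 2 (0.391) or shControl 3 (0.115), after quantile normalization (0.535), median centring (0.0638) or removal of dim genes (0.154), and with trend and robust estimation (0.0683). The median was -0.01 without shKDM1A 1 and -0.11 without shControl 1, where 2 members passed over the list alone, against 0 with all tumours. TGF-beta and SMAD targets were lower for 16 of 23 members, with a median of -0.02 and a mean of -0.05 (camera adjusted p = 0.0252; adjusted p = 0.578 with an estimated correlation). CCN1 differed by -0.21, LTBP1 by -0.14, ID3 by -0.26 and SMAD7 by -0.12. The call was lost without shKDM1A 1 (0.142) or shControl 2 (0.208), without both tumours numbered 1 (0.153), after quantile (0.0900) or cyclic loess (0.108) normalization and without dim genes (0.0903). After quantile or cyclic loess normalization and without dim genes the median itself was further below 0, at -0.05 in each, and it lay at -0.07 without shKDM1A 2, -0.06 without shControl 1, -0.05 without shControl 3, -0.04 without shKDM1A 3 and -0.03 without shKDM1A 1 or shControl 2. Housekeeping reference genes, often taken as unchanging, were lower for 12 of 13 members, with a median of -0.11 (camera adjusted p = 0.000179; adjusted p = 0.578 with an estimated correlation). The transferrin receptor TFRC differed by -0.16, POLR2A by -0.17, CASC3 by -0.16 and IPO8 by -0.20; after cyclic loess normalization 5 members were higher and 8 lower, with a median of -0.03, and the call was lost (adjusted p = 0.103). The median was -0.06 without shKDM1A 1 or after quantile normalization, and 2 members passed over the list alone without shKDM1A 2 and 1 without shControl 1, against 0 with all tumours.

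**Figure D3:**
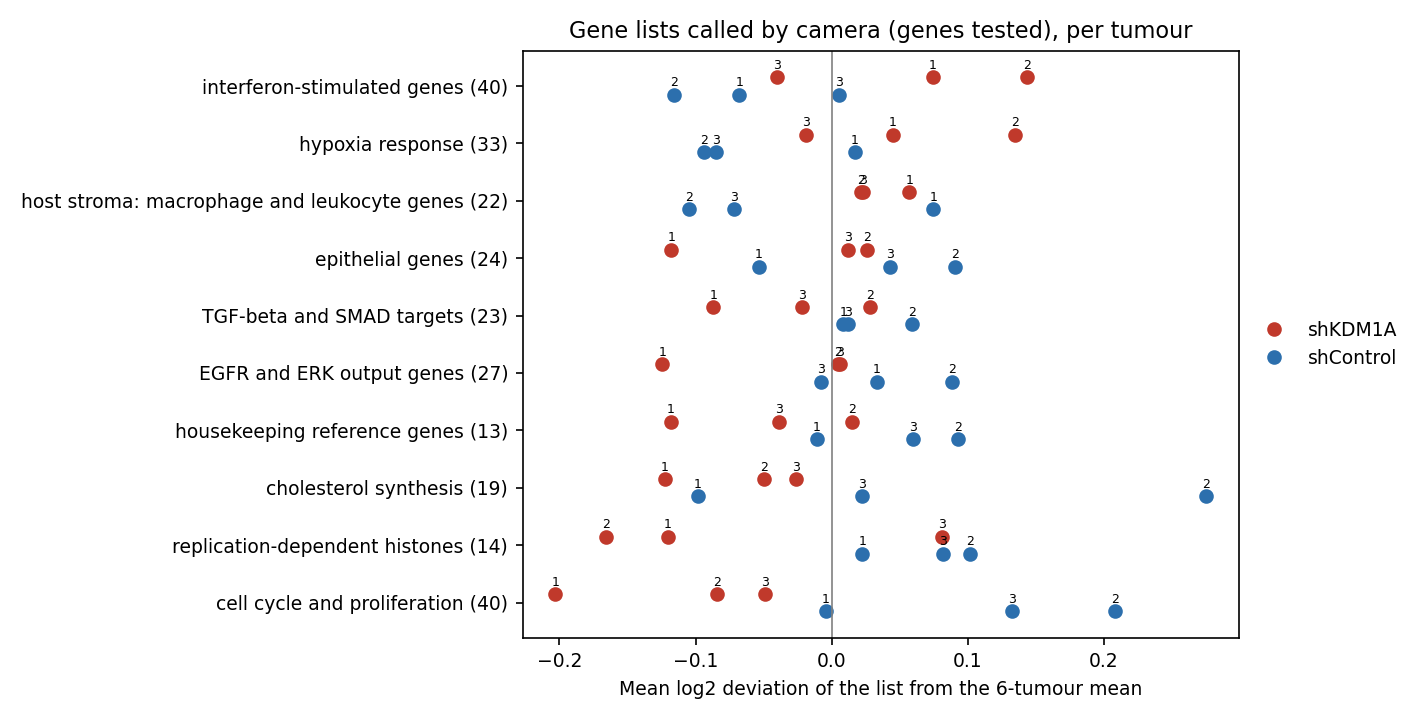
Mean log2 deviation of the tested members of each of the 10 lists called by camera from the mean of the 6 tumours (horizontal axis), 1 point per tumour, numbered by replicate and coloured by labelled group, with the number of genes tested in brackets. The cell cycle list separates the groups, with tumours labelled shKDM1A at -0.20, -0.08 and -0.05, and the groups overlap for the other 9 lists.

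The other 19 lists were not called. Members of KDM1A complexes had a median of -0.01 (camera adjusted p = 0.0819); MTA2, a subunit of a deacetylase complex, differed by -0.31 (SE 0.09) and CHD4 by -0.16. Matrix proteases and their inhibitors had a median of 0.03 (0.571), with MMP19 at 0.10 and MMP3 at -0.10. JNK and AP-1 signalling genes had a median of -0.05 (0.0548), with JUN at -0.23 and MAP3K7 at -0.20. Mesenchymal genes had a median of 0.04 (0.144); S100A4 differed by 0.36 (SE 0.11), integrin ITGA5 by 0.21 and fibronectin (FN1) by 0.66 (SE 0.33). Antigen presentation genes had a median of 0.05 (0.0549), mitochondrial oxidative phosphorylation genes -0.03 (0.0548), neuronal and neuroendocrine genes 0.04 (0.0549), and inflammatory cytokines and NF-kB targets 0.05 (0.0819), with TNF at 0.26. Lung epithelial lineage genes had a median of 0.06 (0.277), and CEACAM6, at -0.35 (SE 0.07), was the 1 member that passed over the list alone. For p53 targets the median was -0.01 (0.381), with GDF15 at 0.27 (SE 0.07), for the unfolded protein response 0.02 (0.663), for Notch signalling 0.02 (0.650) and for angiogenesis factors 0.04 (0.512).

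Genes of glycolysis had a median of -0.04 and a mean of 0.01 (camera adjusted p = 0.381, lower), and ribosomal protein genes a median of -0.00 and a mean of 0.01 (0.855, higher), so that median, mean and test differed in sign. Ribosomal protein genes were called higher after quantile (0.0119) or cyclic loess (0.000302) normalization, and antigen presentation genes likewise (0.0437 and 0.0445). With an estimated correlation neither list was called there (adjusted p = 0.575 for both after quantile and 0.527 for both after cyclic loess normalization). Among lists for other cell types, fibroblast and matrix genes had a median of -0.02 (0.531), with MYL9 at 0.32 and COL1A1 at -0.19. Endothelial genes had a median of 0.03 (0.240), muscle, fat and skin genes 0.04 (0.0819) and red blood cell genes 0.04 (0.390). Fits that left out 1 tumour called 10 of these 19 lists at least once at the preset correlation, and 0 lists with an estimated one.

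Transcripts of pancreatic digestive enzymes stood out in the tumour labelled shControl 1. Pancreatic lipase (PNLIP) had a log2 signal of 6.65 there and 4.45 to 5.23 in the other 5 tumours. Its cofactor colipase (CLPS) had 7.82 there, the amylase AMY2A 4.93, the carboxypeptidase CPB1 4.64 and trypsinogen (PRSS1) 6.24. Of 25 acinar enzyme genes, a list drawn up after most of these levels had been seen, 22 were highest in that tumour, and the tumour labelled shKDM1A 1 ranked next for 16. The median excess of the list in shControl 1 over the median of the other tumours was 0.48. Without both tumours numbered 1, 0 genes passed the adjusted threshold, 2820 had an unadjusted p under 0.05, and 38 of 40 cell cycle genes were lower (camera adjusted p = 6.66e-23; adjusted p = 0.631 with an estimated correlation).

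**Figure D4:**
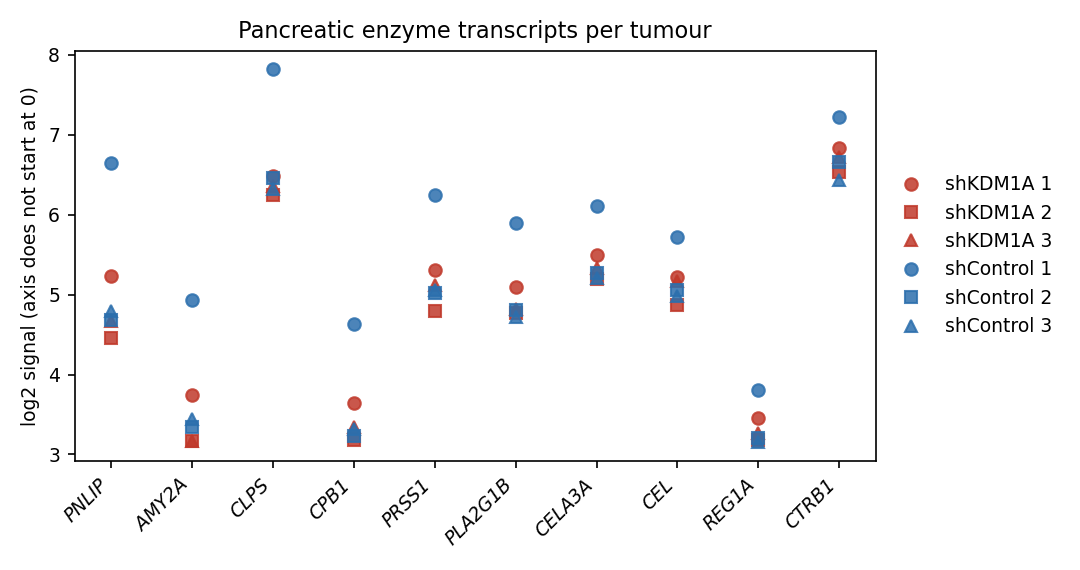
Log2 signal of the 10 acinar enzyme genes with the largest excess in the tumour labelled shControl 1, 1 symbol per tumour, coloured by labelled group and shaped by replicate number. The tumour labelled shControl 1 is highest for each gene, for example at 6.65 for PNLIP and 7.82 for CLPS.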

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

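Cyclic loess normalization, leaving out both tumours numbered 1 and an estimated correlation within the other settings were chosen after the data had been seen; the other alternatives were planned. Of all results under the alternatives, 690 stayed the same, 46 lost a call, 31 gained one, 17 moved and 1 had the direction of its test reversed. Staying the same meant keeping direction and side of the threshold for genes and lists, and staying near the first fit for counts and shares. The 690 include genes and lists that passed in neither fit, so the total does not measure how stable the called lists were. The count of genes past the adjusted threshold stayed at 0 in every refit, where the smallest adjusted p was never under 0.114, and in the unmoderated F-test and the treat test; the rule of an unadjusted p with a 2-fold change gave 1 higher gene, MIR4521. KDM1A stayed lower throughout, from -0.49 to -0.14, and never passed. Dim genes could not be given a value once they were left out, which took away 6 of the 12 single genes named first (KDM1A, TIMP3 and those of smallest p) and the red blood cell list, and other named list members with low signal. The array table holds no background measure, so its limit on dim genes was not assessed. The cause was not tested for any of the changes below except where fewer genes or tumours made them.

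With an estimated correlation the lists called dropped to 0, with adjusted p-values of 0.578 for cell cycle, EGFR and ERK output, interferon, hypoxia, TGF-beta, histone and housekeeping genes, 0.623 for cholesterol and macrophage genes and 0.688 for epithelial genes. Every call added below is at the preset correlation: with an estimated one 0 lists were called under any other setting, with a smallest adjusted p between 0.348 and 0.902. With fry the lists called also dropped to 0, with 0.585 for cell cycle, interferon, hypoxia, TGF-beta, histone, macrophage and housekeeping genes, 0.619 for EGFR and ERK output, 0.621 for cholesterol and 0.694 for epithelial genes. Cyclic loess normalization left the epithelial list with 12 members higher and 12 lower and a median of -0.00, and the direction of its test reversed without a call (0.807); it ended the calls of EGFR and ERK output (0.0655), TGF-beta (0.108), macrophage (0.0655) and housekeeping genes (0.103) and added antigen presentation (0.0445) and ribosomal proteins (0.000302). Quantile normalization ended epithelial (0.535), EGFR and ERK output (0.0607), TGF-beta (0.0900) and macrophage genes (0.0607) and added antigen presentation (0.0437) and ribosomal proteins (0.0119). Median centring gave 35.7% higher genes at an unadjusted p and 0.0638 for epithelial genes. Leaving out dim genes gave 695 genes at an unadjusted p, 30.2% of them higher, with 0.154 for epithelial, 0.0903 for TGF-beta, 0.0264 for mesenchymal and 0.0334 for muscle, fat and skin genes. Trend and robust estimation gave 0.0683 for epithelial genes. Array weights, lowest for shControl 1 (0.354), gave 4938 genes and called KDM1A complexes (0.0406), JNK and AP-1 (0.00800), mitochondrial (0.00582) and neuronal genes (0.0117). Leaving out both tumours numbered 1 gave 2820 genes, called KDM1A complexes (0.0457), mitochondrial (0.0216), neuronal (0.0470) and NF-kB genes (0.0216), and ended EGFR and ERK output (0.241) and TGF-beta (0.153). Array weights moved the TGF-beta median from -0.02 to -0.08 and the cholesterol one from -0.11 to -0.22, with 10 cholesterol and 4 housekeeping members past the threshold over the list alone, against 0 for each. All clusters together gave 3168 at an unadjusted p, 62.2% of them higher.

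The replicate number as a block gave 0 genes past the adjusted threshold, 2027 at an unadjusted p against 1301, and called mitochondrial genes (0.0427); it changed no other call. Whether the numbers pair the tumours was not settled. Deviations of same-numbered tumours correlated at 0.305, 0.272 and -0.158 across genes. Among the control tumours, shKDM1A 1 and shKDM1A 2 correlated best with the one of their own number, and shKDM1A 3 did not.

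Leaving out 1 tumour at a time moved the genes at an unadjusted p between 695 and 3870 and the lists called between 5 (without shControl 2) and 15 (without shKDM1A 3), with 6 without shKDM1A 1. The cell cycle, histone, interferon and housekeeping lists were called in all 6 fits at the preset correlation. Adjusted p-values ran from 0.00178 to 0.534 for epithelial genes, 0.000644 to 0.230 for EGFR and ERK output, 1.67e-08 to 0.110 for hypoxia, 2.70e-06 to 0.364 for cholesterol, 0.00327 to 0.208 for TGF-beta and 0.00771 to 0.310 for macrophage genes. Among lists not called, they ran from 0.0328 (without shControl 1) to 0.310 for KDM1A complexes, 0.00840 (without shControl 3; 0.0113 without shKDM1A 2) to 0.315 for JNK and AP-1, 0.0183 (without shKDM1A 3) to 0.533 for mesenchymal genes, 0.0250 (without shKDM1A 3; 0.0370 without shControl 3) to 0.438 for antigen presentation, 0.0349 (without shKDM1A 2) to 0.892 for glycolysis, 0.00178 (without shControl 1; 0.00512 without shKDM1A 3) to 0.834 for mitochondrial genes, 0.0352 (without shControl 1) to 0.992 for lung lineage genes, 0.0216 (without shControl 1; 0.0389 without shKDM1A 2) to 0.310 for neuronal genes, 0.0218 (without shKDM1A 3; 0.0283 without shControl 1) to 0.474 for NF-kB genes and 0.00914 (without shKDM1A 3; 0.0315 without shControl 3) to 0.474 for muscle, fat and skin genes.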

Other observations

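The genes named here and the tests in this part were chosen after the results were seen; only for the tests that use cyclic loess normalization was the deciding outcome written down before they were run, and that normalization was itself an added choice.

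Several genes outside the fixed lists differed by more than 1.5-fold with separated groups, none past the adjusted threshold (limma adjusted p = 0.835 for each). DIO2, the deiodinase that activates thyroid hormone, differed by -0.64 (SE 0.13), with 6.42, 6.41 and 6.53 in the tumours labelled shKDM1A and 6.78, 7.36 and 7.14 in those labelled shControl. TMEM63C, a membrane channel protein, differed by 0.77 (SE 0.16), the antimicrobial peptide psoriasin (S100A7) by 0.74 (SE 0.18) and PAPPA, a protease that cleaves IGF-binding proteins, by 0.63 (SE 0.20).

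MMP13, IFI6 and CASP14 had the same 3 tumours highest, and these crossed the labels; other genes with large differences did not share this, and MIR4521 was highest in shKDM1A 1 (4.61), shKDM1A 3 (4.30) and shControl 1 (3.14). MMP13 had 7.51 and 7.33 in the tumours labelled shKDM1A 1 and 2 and 6.61 in shControl 3, against 5.62 in shKDM1A 3, 5.32 in shControl 1 and 4.75 in shControl 2. IFI6 had 8.21 in shKDM1A 2 and 7.36 in shKDM1A 1, with 6.88 in shControl 3 and 6.04 in shKDM1A 3. CASP14, a caspase of differentiating skin, was highest in shKDM1A 2 (8.38) and shKDM1A 1 (7.47), and had 7.40 in shControl 3.

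Setting the tumours labelled shKDM1A 1, shKDM1A 3 and shControl 1 against the rest gave 5536 genes at an unadjusted p under 0.05 and 17 lists (0 with an estimated correlation), against 1301 genes and 10 lists for the labelled groups, which points to a structure of the samples. These 3 tumours also had the highest array medians (3.41, 3.39 and 3.41 against 3.31 to 3.36) and the highest means of 1041 small RNA genes (4.47, 4.37 and 4.44 against 4.31 to 4.36), so a difference in array scale or RNA quality stays open. An array effect that depends on signal strength did not account for all of it, because the split gave 4258 genes after cyclic loess normalization, although the lists dropped to 4. For swapped labels of shControl 1 and shKDM1A 2, the KDM1A values went both ways. KDM1A lay 0.42 lower in shKDM1A 2 than in the lower of shControl 2 and 3, beyond a pooled SD of 0.22, unlike a control tumour. In shControl 1 it lay inside the range of the tumours labelled shKDM1A, as a swap would give. The labelled difference in KDM1A did not pass either, so this gene cannot decide on a swap. A wrong label of shControl 1 alone may still hold. Its KDM1A lay inside the range of the knockdown tumours, and its cell cycle mean only 0.045 above the highest of them. Its cell cycle minus epithelial mean (0.05 against at most -0.06) and TIMP3 (6.40 against 6.55 to 6.57) lay on the control side. Both were taken up for this question after the results were seen, and both separate the labelled groups. Separation was seen for 9.74% of all genes, where chance gives 10%. They therefore do not weigh against a wrong label, and such an error is neither shown nor excluded.

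The pancreatic enzyme transcripts may come from RNA of pancreatic tissue in the sample labelled shControl 1. Of the acinar genes 88% were highest there, and 16 of 19 once the 6 that drew attention to the pattern were set aside; because most levels had been seen when the list was written, this test is not independent. An array effect of signal strength is argued against, since cyclic loess normalization left 94.1% of the median excess. Islet genes (6 measured, median excess 0.07, 3 highest there) and secreted liver proteins (12 measured, 0.05, 6 highest) stood near the other tumours, and none of the 25 acinar genes is in the 29 lists. Whether such RNA was human or murine, how it entered the sample, and whether the tumour cells made the transcripts themselves stay open; no biological explanation was tested.

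The cell cycle list was lower in the tumours labelled shKDM1A, and no table measures growth, so an effect of the knockdown on proliferation was not tested. Signal strength is argued against, because cyclic loess normalization left 93.9% of the median difference. The epithelial list was taken as a measure of tumour cells, which was not checked, and 17 of its 24 members were lower and 7 higher. The cell cycle mean minus the epithelial mean differed between the groups by -5.73 pooled SD (-0.09, -0.11 and -0.06 against 0.05, 0.12 and 0.09). The cell cycle list was thus lower relative to the epithelial list. This argues against a lower share of tumour cells as the whole cause only if that list measures the share. The reference was chosen after the results were seen. Housekeeping genes, another possible reference, had overlapping mean deviations of -0.12, 0.01 and -0.04 against -0.01, 0.09 and 0.06. A lower share of tumour cells as part of the cause stays open in any case. Housekeeping genes were lower (median -0.11, or -0.03 after cyclic loess normalization), and so were epithelial genes (-0.07, or -0.00 with 12 higher and 12 lower). Macrophage and leukocyte genes were higher (0.07, or 0.06). None of these 3 lists was called after that normalization. Fibroblast genes had -0.02 and endothelial genes 0.03. Growth that varies between tumours regardless of the shRNA cannot be told apart from a knockdown effect: with an estimated correlation the adjusted p was 0.578. The labelled split separated the list furthest, 1 of the 10 splits doing so, with a difference in list mean of -0.22. Splits across the labels came close. The difference was -0.19 for shKDM1A 1, shKDM1A 2 and shControl 1 against the rest. It was -0.17 for shKDM1A 1, shKDM1A 3 and shControl 1, the tumours with the highest array medians. The remaining splits lay between -0.10 and 0.09. The difference in array scale or RNA quality left open above also runs partly along the labels. The tumours labelled shControl 2 and 3 had the lowest array medians (3.33 and 3.31) and the highest cell cycle means (0.21 and 0.13). Centring on array medians left the list median at -0.24, but a part of RNA quality in the list was not tested.

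Other splits of the 6 tumours bear on the counts as follows. Of the 10 splits into 3 and 3, 3 gave at least the 1301 genes at an unadjusted p under 0.05 of the labelled split, with 5536 as the highest other. For the 10 lists called, 4 of the 10 splits gave as many, with 17 as the highest other. For genes past the adjusted threshold, all 10 splits gave as many as the labelled one, which had 0, with 0 as the highest other. The 10 splits are too few for a share under 0.05.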
